A study of Rattus norvegicus with 12 samples.

How the data were processed

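Gene expression was measured in rat calvaria, the bone of the skull roof, on 12 Agilent arrays of 1 colour (Cy3), 4 for each of 3 groups. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and 200 ng of total RNA was labelled. Each group was taken from the labels, which also number the samples 1 to 4 within it. No label says whether the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

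The scanner output of each array was deposited as spot intensity on a linear scale. Per the file headers it was made with Agilent Feature Extraction 11.0.1.1, protocol GE1_1100_Jul11, and the probe positions are those of genome build rn4. The deposited processed intensity is background-subtracted and detrended within the array per the file headers, and is not normalized between arrays. The authors also deposited a table of log2 values, named as quantile-normalized, and 3 comparison tables with log2 changes and p-values whose column names are those of limma. The processing between scanner output and table is not given in the sources used here. Over the lines also in the comparison tables, the Spearman correlation of the deposited log2 values with the log2 median spot signal of the same array was 0.978 to 0.982, and over the other lines 0.895 to 0.940. Column medians of the deposited log2 values were 7.18 to 7.32 on the log2 scale. Of its 24920 lines, 1651 were in none of the comparison tables and were left out, and 1531 of these repeat a probe.

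Each array held 62976 spots, of which 58717 were not control spots and carried 45598 probes. Values were log2 of the processed intensity minus the log2 of the array's 75th percentile over non-control spots. Spots with an outlier flag were left out, except where every spot of a probe on an array was flagged, and spots of the same probe were averaged. No spot was saturated. A probe was kept where it was well above background on at least 4 of the 12 arrays, which left 29775 probes. The brightest kept probe stood for each gene name, giving 22718 genes, 14483 of them with a gene symbol. Among the 5375 genes with more than 1 kept probe, probes were called in opposite directions for 23 in laser against control and for 41 in bur against control. Gene names are those of the array design. The accessions of 21184 probes were found in a reference gene table of assembly GRCr8, which gave another current symbol for 2431 of them, and no coordinate was taken from that table.

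Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with lmFit and eBayes on all 12 arrays and a mean for each group, two-sided. Adjusted p-values are Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Where a gene was not well above background on any array of a group, its change is a bound, given as "at least N-fold". The bound sets the brighter group's mean against a floored mean of the dimmer group. Per array, this took the higher of the probe's own signal and the lowest signal among probes well above background. That lowest signal is not the detection limit of the probe itself, so the bound is approximate and the true change can be smaller.

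For gene lists, limma's camera was used with a preset inter-gene correlation of 0.01 over 31 lists of bone, wound, stress and cell type genes, each with at least 5 measured members, adjusted over the lists. The same test with an estimated correlation, limma's fry and an exact permutation of list means were alternatives. The smallest two-sided p that an exact permutation of 4 against 4 arrays allows is 0.0286.

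Before the data were examined, the groups, tests, lists, alternatives and the rule for naming genes were fixed. The rule took Sost, then the 10 symbols with the largest rise and the 10 with the largest fall among genes past the threshold whose values did not overlap between groups. From each described list it allowed up to 4 passing members with the largest change, or, with none passing, the member with the smallest p as values only. Which of the allowed list members are named here was chosen after their values were seen. Some genes that the rule took are not reported here.

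Whether the replicate numbers pair the samples was decided from the correlations of same-numbered arrays' deviations from their group means. These were 0.25, 0.24, 0.16 and 0.34 between bur and laser and 0.34, 0.18, 0.22 and 0.13 between control and laser, all above 0.1. Between bur and control they were 0.28, -0.05, 0.28 and 0.08. The numbers were therefore taken to pair laser with each other group, and not bur with control. Since both of these are taken as paired with laser, a pairing of bur with control is not excluded. Arrays of different numbers reached 0.143 between bur and laser, 0.125 between control and laser and 0.32 between bur and control. A correlation above 0.1 alone thus does not part paired from unpaired arrays. The medians for different numbers were -0.09, -0.07 and -0.07. The limma fit first chosen used no pairing, and restricting splits to those that part the pairs was chosen after results were seen. Per the file headers the number is also the array's place on its slide.

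The model was tested on simulated data made from the 22718 genes, with 50 genes changed at each of 4 sizes. Of 50 genes changed by 1 on the log2 scale, 22 were called in laser against control, 29 in bur against control and 26 in laser against bur. Of 50 changed by 2, the calls were 46, 45 and 40, and of 50 changed by 0.5 they were 2, 1 and 4. Unchanged genes gave 6, 4 and 7 false calls. Far fewer genes were changed than limma called against control in the data, which makes the adjusted threshold stricter. Each gene also had the same spread in all groups. The shares recovered are therefore not those of the real comparisons with control. A shifted list was called in each simulated comparison, and of 30 lists without a shift 1 was falsely called in laser against control, 0 in bur against control and 1 in laser against bur. Genes were simulated as independent, with 1 draw per comparison, so the members of a list were uncorrelated. These numbers are therefore not the false-call rates of the list test in the data.

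Alternatives were other background corrections, normalizations, filters and probe rules, an intensity trend and array weights. Others were the replicate number as a block, fits on the 2 groups compared, and fits without each array. As a further alternative, the authors' deposited log2 values of 20513 of the genes were put through the same fit. As a setting, "the deposited table" means this refit and not the authors' comparison tables. A marrow score as covariate (the mean of the erythroid, neutrophil and B cell lists on each array) and the exact permutation of list means were added after the data were seen. The slide as a block could not be fitted.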

Results

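Rat calvarial bone was profiled 72 h after surgery. A defect of 8 by 3 mm had been made in bone of rats aged 10 weeks, either with an Er:YAG laser, an infrared laser that ablates mineralised tissue, or with a rotating bur. The laser ran at 20 Hz with an output of 127 mJ per pulse. Per the treatment protocol the periosteum was taken off control bone, which was not ablated, while the series design calls the controls non-treated, so it is open whether control bone had surgery. Each group had 4 arrays, and their number limits the precision. Between 58.1% and 67.0% of probes were well above background on each array. Correlations between arrays of a group were 0.948 to 0.980 for control, 0.979 to 0.983 for bur and 0.97 to 0.98 for laser. All 4 control arrays were on 1 slide and all 8 treated arrays on another, each slide scanned apart, with bur in column 1 and laser in column 2. Slide, scan and group therefore cannot be told apart in either comparison with control, nor slide column and group in the comparison of laser with bur. Control replicate 3 lay nearer to the treated arrays than the other controls did. On the first principal component, with 49.5% of the variance, it was at 6.67, against 102, 55.5 and 122 for control replicates 1, 2 and 4 and -53.1 to -7.43 for the treated arrays.

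The series is about Sost, which encodes sclerostin, an inhibitor of Wnt signalling made by osteocytes. Its probe lies on chromosome 10 at 91026551 to 91026610 of rn4. The signal of Sost, on the log2 scale relative to the array's 75th percentile, was -3.20 ± 0.23 in control, -3.09 ± 0.49 in bur and -3.17 ± 0.72 in laser bone (SD, n = 4 each). The differences were smaller than this spread. Laser minus control was 0.02 (SE 0.34, 95% interval -0.72 to 0.76, limma adjusted p = 0.97). Bur minus control was 0.10 (interval -0.64 to 0.84, limma adjusted p = 0.85), and laser minus bur was -0.08 (interval -0.82 to 0.66, limma adjusted p = 0.9998). The authors' own comparison tables give 0.07, 0.12 and -0.05 for the same comparisons. Laser replicate 2 was far below the other laser arrays, at -4.25, and without it laser minus control was 0.38 (limma adjusted p = 0.30) and laser minus bur was 0.28. With normexp background correction the differences were -0.08, -0.11 and 0.02, but the median of all genes then moved to -0.08, -0.24 and 0.13. Relative to these medians Sost was near 0 in laser minus control and kept its sign in the other comparisons.

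**Figure D1:**
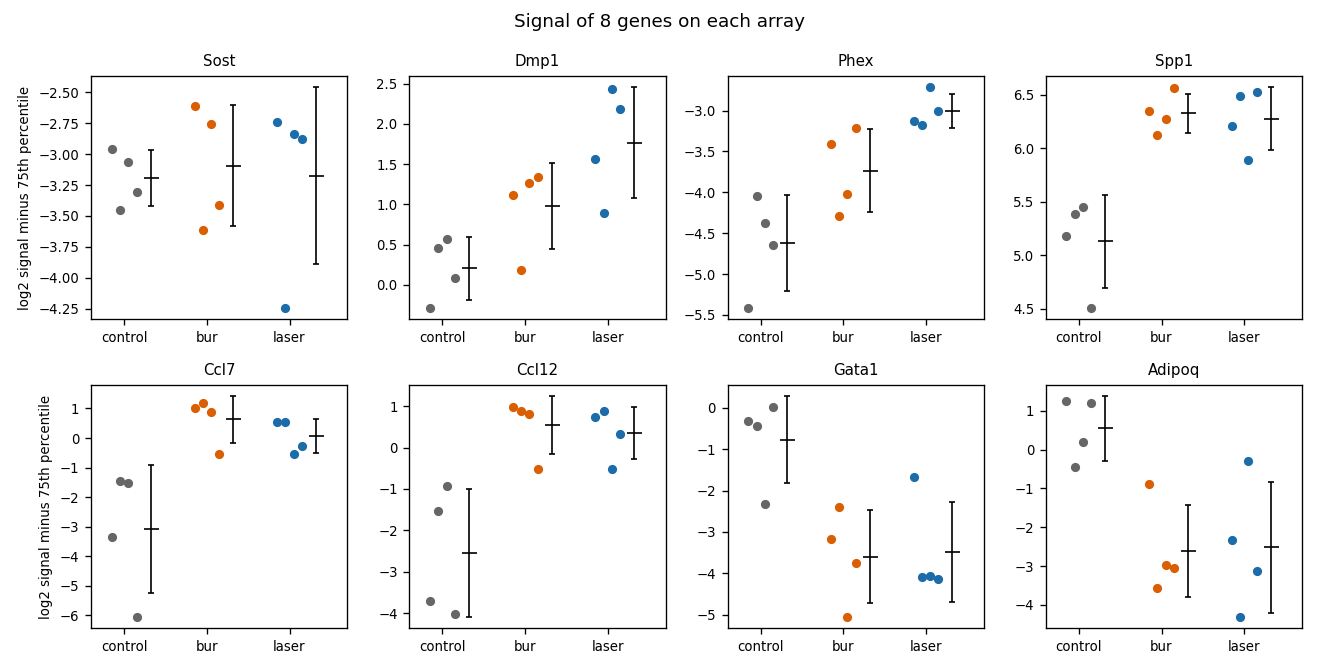
Log2 signal relative to the array's 75th percentile for 8 genes, with 1 point per array and, beside the points, the mean and SD of the 4 arrays of each group. Sost overlapped between groups, with 1 laser array at -4.25, while the treated arrays lay above every control array for Spp1, Ccl7 and Ccl12.

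Laser-ablated bone was compared with control bone to see what ablation changed. Chemokine genes were among the largest rises, while the list of inflammatory cytokine and chemokine genes did not pass (7 of 22 rose and 3 fell, and 11 and 3 when adjusted over the list alone, camera adjusted p = 0.21, and 0.039 with normexp). Ccl7 went from -3.09 ± 2.17 to 0.07 ± 0.56 (SD, n = 4), a log2 rise of 3.17 (SE 0.86, limma adjusted p = 0.028). It passed in 8 of the 12 fits that each left out an array, and not in a fit on these 2 groups alone (limma adjusted p = 0.0645). Cxcl3 rose by 3.25 (SE 0.76) and Ccl12 by 2.91 (SE 0.66), and Il11, a cytokine gene, rose by 2.90 (SE 0.53, limma adjusted p = 0.0086). Pax1, a transcription factor gene of the developing axial skeleton, was not well above background on any control array and was at least 6.52-fold higher with laser. The same held for Lipi, at least 6.73-fold higher, and Slc27a5, at least 6.05-fold. Adgra1 rose by 3.92 (SE 0.84) and Rln1, which encodes a relaxin, by 2.90 (SE 0.41).

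Among the largest falls, Lep, which encodes leptin, fell by 3.91 on the log2 scale (SE 0.83, limma adjusted p = 0.015), and Gys2, a glycogen synthase gene, fell by 3.06 (SE 0.78). Pck1, the gene of a gluconeogenic enzyme, was not well above background on any laser array and was at least 3.70-fold lower. Suv39h2, a histone methyltransferase gene, fell by 3.51 (SE 0.49). Prp15 fell by 3.62, Ecel1 fell by 3.39, Slc7a10 fell by 3.12 and Atad2 fell by 3.05. Pom121l2 fell by 3.55, but only 1 of its 2 kept probes had that sign. With normexp, the changes of Pax1 (0.57), Adgra1 (0.78), Lipi (0.49), Cxcl3 (1.07), Slc27a5 (0.43) and Pck1 (-0.48) no longer passed.

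Lists of osteocyte, osteoblast, osteoclast regulator and cartilage genes stood higher with laser, while that of osteoclast genes did not pass (1 of 14 rose and 1 fell, the same when adjusted over the list alone, camera adjusted p = 0.89). Of 9 measured osteocyte genes 7 rose and none fell, and 8 passed when adjusted over the list alone (camera adjusted p = 4.9e-04; adjusted p = 0.53 with an estimated correlation). Examples were Phex, 1.62 (SE 0.30), Dmp1, 1.56 (SE 0.36), Mepe, 1.37 (SE 0.36), and Pdpn, 1.41 (SE 0.42). Of 18 osteoblast and bone matrix genes 6 rose, 2 fell and 10 did not pass, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0085; adjusted p = 0.57 with an estimated correlation). Phospho1 rose by 1.34, Spp1, which encodes osteopontin, by 1.15, and Alpl, which encodes the alkaline phosphatase of mineralising cells, by 1.03. Of 7 osteoclast regulators 2 rose, and 2 when adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.53 with an estimated correlation). They were Tnfsf11, which encodes RANKL, at 1.87 (SE 0.46), and Csf1 at 0.58 (SE 0.18, limma adjusted p = 0.039, and 0.053 with the replicate number as a block). Of 8 cartilage genes 3 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.53 with an estimated correlation), among them Acan at 1.75 (SE 0.56) and Ihh at 1.03 (SE 0.19). With normexp, Tnfsf11 (0.09), Acan (0.47) and Ihh (0.45) no longer passed.

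Of 24 fibrous matrix and matrix remodelling genes 7 rose and none fell, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.8e-05; adjusted p = 0.53 with an estimated correlation). Has2, a hyaluronan synthase gene, rose by 2.41 (SE 0.79) and Tnc, which encodes tenascin C, by 1.72 (SE 0.39). Of 19 hypoxia and glycolysis genes 6 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.57 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 2.10 (SE 0.60) and the collagen hydroxylase gene P4ha2 by 1.38 (SE 0.33). Of 15 macrophage and monocyte markers 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.0085; adjusted p = 0.53 with an estimated correlation). They were Trem2 at 2.29 (SE 0.72), Cd14 at 1.79 (SE 0.36) and Msr1 at 1.59 (SE 0.48). Of 15 interferon response genes 3 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.62 with an estimated correlation). Usp18 rose by 1.94 (SE 0.45), Oasl was at least 4.16-fold higher, and Rsad2 fell by 2.43 (SE 0.51). With normexp Oasl (0.31) no longer passed.

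Markers of blood cell lineages, dividing cells and fat cells were lower with laser. Of 15 erythroid markers 14 fell, and 15 when adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.53 with an estimated correlation). The erythroid transcription factor gene Gata1 fell by 2.72 (SE 0.71). Of 13 neutrophil markers 6 fell, and 11 when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.53 with an estimated correlation), with Camp at -1.92 (SE 0.52) and S100a9 at -1.53 (SE 0.48, limma adjusted p = 0.041, and 0.075 with quantile normalization). Of 10 mast cell markers 9 fell, and 10 when adjusted over the list alone (camera adjusted p = 8.6e-06; adjusted p = 0.53 with an estimated correlation), with Hdc at -2.27 (SE 0.49) and Cma1 at -2.12 (SE 0.35). Of 12 B cell markers 2 fell, and 2 when adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.57 with an estimated correlation), with Ms4a1 at -1.64. Of 13 T cell and NK cell markers 5 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.53 with an estimated correlation; adjusted p = 0.057 with the replicate block). Cd3e was at -1.95 and at -0.47 with normexp, where it no longer passed, and Cd247 was at -1.58. Of 28 cell cycle genes 12 fell and none rose, and 20 fell when adjusted over the list alone (camera adjusted p = 6.5e-07; adjusted p = 0.54 with an estimated correlation), with Plk1 at -1.42 (SE 0.34) and Mki67, a marker of dividing cells, at -1.21 (SE 0.37). Of 9 adipocyte markers 7 fell, and 7 when adjusted over the list alone (camera adjusted p = 7.4e-04; adjusted p = 0.53 with an estimated correlation), with Adipoq, which encodes adiponectin, at -3.07 (SE 0.81). The marrow score, the mean of the erythroid, neutrophil and B cell lists relative to the mean of the 12 arrays, was 1.30, 0.76, 0.11 and 2.07 on control replicates 1 to 4 and -1.20 to 0.13 on treated arrays.

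In all, limma called 2103 genes higher and 2958 lower with laser among 22718. Of these, 902 rose and 1477 fell at least 2-fold. The groups did not overlap for 19.0% of genes, against 2.86% by chance for unpaired arrays. The authors' own comparison table calls 3534 higher and 3452 lower among its 23269 lines. With the marrow score as a covariate, an alternative chosen after the data were seen, the counts were 2 and 0, and the median size of change of the called genes went from 0.96 to 0.43 while its median SE went from 0.24 to 0.29. The counts leaned on single arrays. Without control replicate 1 they were 449 and 796, without laser replicate 2 they were 517 and 801, without laser replicate 3 they were 529 and 998, without control replicate 4 they were 831 and 1143, and without laser replicate 4 they were 1036 and 1596. Without control replicate 2, 1964 were lower, and without control replicate 3, 3861 were higher. A fit on these 2 groups alone called 651 and 1107. Of the 58 passing genes named for this comparison 25 passed whichever array was left out, while 32 lost the call without control replicate 1, 27 without laser replicate 3, 25 without laser replicate 2, 19 without control replicate 4 and 14 without laser replicate 4. The interferon list lost its call without laser replicate 1 (camera adjusted p = 0.055), 2 (0.12) or 3 (0.058) or control replicate 2 (0.080), 3 (0.073) or 4 (0.053). The T cell and NK cell list lost it without laser replicate 1 (0.055) or 4 (0.055), control replicate 1 (0.063), 3 (0.078) or 4 (0.058), or bur replicate 2 (0.057). Without control replicate 4 the cartilage genes (0.058) and osteoclast regulators (0.081) lost theirs. Array weights ended the calls of the osteoblast (0.073), osteoclast regulator (0.068), B cell (0.097) and T cell and NK cell lists (0.12), and the mean of probes that of the osteoclast regulators (0.071). A filter asking for detection on all 12 arrays ended those of the cartilage (0.056), adipocyte (0.13) and interferon lists (0.072), and the percentile over detected probes also that of the interferon list (0.064). With the marrow score as covariate the osteocyte, mast cell and adipocyte lists passed, and the other lists described for this comparison did not.

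Calls of single genes with laser leaned on arrays and settings too. Of the 12 fits that each left out an array, Has2 and Trem2 passed in 2, Acan and S100a9 in 3, Csf1 and Msr1 in 4, Mki67 in 5, and Gata1, Camp, Ms4a1 and Pdpn in 6. With array weights Has2 was at 1.39 (limma adjusted p = 0.078), Trem2 at 1.35 (0.095), Msr1 at 1.003 (0.072) and Adipoq at -2.26 (0.071), none of which passed. Without the detection filter the calls of Has2 (0.074), Trem2 (0.066), Acan (0.071), Csf1 (0.070), Msr1 (0.061), Mki67 (0.063), Ms4a1 (0.063), Pdpn (0.059), S100a9 (0.065) and Slc2a1 (0.0502) ended. S100a9 did not pass in the deposited table's values (0.061), nor Csf1 with the mean of its probes, at 0.34 (0.12). A fit on these 2 groups alone ended the calls of 21 of the 58 named genes, Has2 (0.10), Trem2 (0.091) and Msr1 (0.064) among them. Some probes were near background in the dimmer group. Adgra1 and Tnfsf11 were well above background on 1 of 4 control arrays, and Il11 and Has2 on 2, while Lep and Pom121l2 were so on 1 of 4 laser arrays, and Atad2 and Cd3e on 2, so the sizes of these changes rest partly on signal near background.

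**Figure D2:**
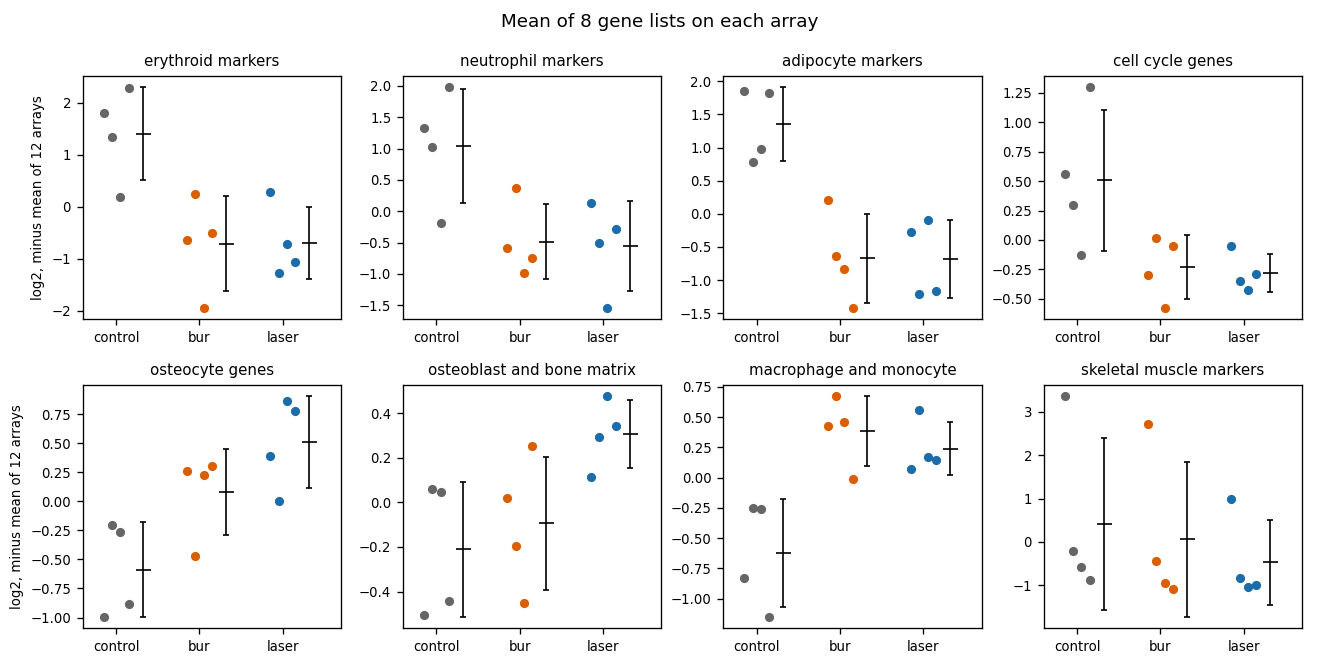
Mean log2 signal of the measured members of 8 gene lists, relative to the mean of the 12 arrays, with 1 point per array and the mean and SD of the 4 arrays of each group beside them. Control replicate 3 had the lowest erythroid, neutrophil and cell cycle means of the controls, and replicate 1 of every group had the highest skeletal muscle mean of its group, at 3.37 in control, 2.72 in bur and 0.98 in laser.

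Bur-drilled bone was compared with control bone in the same way. Chemokine and metalloproteinase genes were among the largest rises. The list of inflammatory cytokine and chemokine genes did not pass (8 of 22 rose and 2 fell, and 9 and 2 when adjusted over the list alone, camera adjusted p = 0.057), and no list of proteases was tested. The cytokine and chemokine list passed with the replicate number as a block (0.027), but with the block and an estimated correlation the smallest adjusted p of any list was 0.53. It also passed with normexp (0.0035), without the detection filter (0.0056), with the mean of probes (0.042), and without bur replicate 4 (0.0016), control replicate 1 (0.042), control replicate 2 (0.021) or laser replicate 2 (0.049). Ccl7 went from -3.09 ± 2.17 to 0.63 ± 0.79 (SD, n = 4), a log2 rise of 3.73 (SE 0.86, limma adjusted p = 0.013). Ccl2 rose by 3.23 (SE 0.73), Ccl12 by 3.09 (SE 0.66) and Cxcl3 by 3.37 (SE 0.76). The metalloproteinase genes Mmp12 and Mmp7 rose by 3.73 (SE 0.80) and 3.44 (SE 0.87), Anxa8 by 3.11 (SE 0.75) and Card14 by 2.82 (SE 0.65). Pax1 was at least 8.19-fold higher, not being well above background on any control array. With normexp Pax1 (0.51) and Card14 (0.22) no longer passed.

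The largest falls overlapped those seen with laser. Gys2 fell by 4.47 (SE 0.78), Lep fell by 4.27 (SE 0.83), Prp15 fell by 4.22 (SE 0.74), Suv39h2 fell by 4.02 (SE 0.49) and Rnls fell by 3.62 (SE 0.77). Slc7a10 fell by 3.79, Ecel1 fell by 3.78 and Csf3, which encodes the granulocyte growth factor G-CSF, fell by 3.30. Pck1 was at least 4.96-fold lower. Pom121l2 fell by 3.41, with that sign in 1 of its 2 kept probes.

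Among bone genes, 1 of 9 osteocyte genes rose, Pdpn at 1.29 (SE 0.42), and 0 when adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.70 with an estimated correlation). Of 18 osteoblast and bone matrix genes 1 rose and 2 fell, and the same numbers when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.62). Spp1 rose by 1.20 (SE 0.22), Dlx3, a homeobox gene of osteoblasts, fell by 1.11 (SE 0.17), and Pth1r, the receptor gene for parathyroid hormone, fell by 0.86 (SE 0.15) with that sign in 1 of 2 kept probes. Pth1r did not pass with the mean of its probes (-0.40). Of 7 osteoclast regulators 2 rose, and 2 when adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.70 with an estimated correlation), Tnfsf11 at 1.58 (SE 0.46) and Csf1 at 0.74 (SE 0.18). With normexp Tnfsf11 no longer passed and turned to -0.15, while the median of all genes moved to -0.24.

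Of 24 fibrous matrix genes 8 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.3e-04; adjusted p = 0.70 with an estimated correlation), with Has2 at 2.50 (SE 0.79) and the protease inhibitor gene Timp1 at 1.55 (SE 0.41). Of 19 hypoxia and glycolysis genes 6 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.70 with an estimated correlation), with Slc2a1 at 2.22 (SE 0.60) and Ndrg1 at 1.66 (SE 0.43). Of 15 macrophage and monocyte markers 6 rose, and 9 when adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.70 with an estimated correlation), with Arg1 at 2.82 (SE 0.96), Trem2 at 2.40 (SE 0.72) and Cd14 at 2.03 (SE 0.36). Of 15 heat shock and unfolded protein genes 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.70 with an estimated correlation). Hmox1, which encodes haem oxygenase, rose by 1.52 (SE 0.50), Hspb1 by 1.05 (SE 0.34) and the chaperone gene Hspa5 by 0.73 (SE 0.19).

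All 15 erythroid markers fell, and 15 when adjusted over the list alone (camera adjusted p = 9.1e-06; adjusted p = 0.70 with an estimated correlation), with Gata1 at -2.82 (SE 0.71) and the haem synthesis gene Alas2 at -2.75 (SE 0.64). Of 13 neutrophil markers 5 fell, and 10 when adjusted over the list alone (camera adjusted p = 8.4e-04; adjusted p = 0.70 with an estimated correlation), with Prtn3 at -2.08 and Camp at -1.89 (SE 0.52 each). Of 10 mast cell markers 8 fell, and 9 when adjusted over the list alone (camera adjusted p = 3.6e-04; adjusted p = 0.70 with an estimated correlation), with Hdc at -2.09 and Cma1 at -1.80. Of 12 B cell markers 3 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.0091; adjusted p = 0.70 with an estimated correlation). Of 28 cell cycle genes 13 fell, and 16 when adjusted over the list alone (camera adjusted p = 2.1e-05; adjusted p = 0.70 with an estimated correlation), with Plk1 at -1.48 and Mki67 at -1.12. Of 9 adipocyte markers 7 fell, and 7 when adjusted over the list alone (camera adjusted p = 0.0048; adjusted p = 0.70 with an estimated correlation), with Adipoq at -3.17 (SE 0.81). The list did not pass with normexp (camera adjusted p = 0.058). The marrow score was -0.68, 0.06, -1.20 and -0.28 on bur replicates 1 to 4, below the 1.30, 0.76 and 2.07 of control replicates 1, 2 and 4, while control replicate 3 was at 0.11.

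In all, limma called 2270 genes higher and 3678 lower with bur, 913 and 1687 of them at least 2-fold, and the groups did not overlap for 25.3% of genes against 2.86% by chance. Of the calls 38.2% were higher, and 20.7% with normexp, where the median of all genes moved to -0.24. The authors' own comparison table calls 3692 higher and 3941 lower among its 23269 lines. With the marrow score as a covariate, chosen after the data were seen, both counts were 0, and the median size of change of the called genes went from 0.92 to 0.47 while its median SE went from 0.22 to 0.28. Without control replicate 1 the counts were 878 and 1911, without bur replicate 1 they were 1210 and 2385, without bur replicate 3 they were 1211 and 2197, and without control replicate 4 they were 1476 and 2273. Without bur replicate 4, 1352 were higher, and without control replicate 3, 3794 were. A fit on these 2 groups alone called 1483 higher. Of the 50 passing genes named for this comparison 33 passed whichever array was left out, while 16 lost the call without control replicate 1, 12 without bur replicate 3 and 10 without control replicate 4. Without control replicate 4 the osteocyte list (camera adjusted p = 0.057), osteoclast regulators (0.19), B cell markers (0.057) and heat shock genes (0.053) lost their calls, and without bur replicate 3 the osteoclast regulators (0.052) and heat shock genes (0.087) did. The osteoclast regulators also lost theirs with quantile normalization (0.056), detection on all 12 arrays (0.12), the mean of probes (0.15), the percentile over detected probes (0.057) and array weights (0.13). Array weights ended the calls of the osteocyte (0.13) and B cell lists (0.090) as well, and detection on all 12 arrays that of the adipocyte list (0.35). With the marrow score as covariate only the adipocyte list passed.

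Among single genes with bur, Arg1 and Hspb1 passed in 2 of the 12 fits that each left out an array, Mki67 in 3, Hmox1 in 4, Pdpn in 5 and Trem2 in 6. With array weights Arg1 was at 2.08 (limma adjusted p = 0.077), Trem2 at 1.43 (0.067) and Pdpn at 0.84 (0.068), none of which passed. Without the detection filter the calls of Arg1 (0.054) and Mki67 (0.05002) ended, and with the mean of probes that of Arg1 (0.051) did. A fit on these 2 groups alone ended the calls of 8 of the 50 named genes, Arg1 (0.081) and Trem2 (0.067) among them. Card14 and Tnfsf11 were well above background on 1 of 4 control arrays and Has2 on 2, while Lep was so on 1 of 4 bur arrays, and Gys2 and Pom121l2 on 2, so the sizes of these changes rest partly on signal near background.

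The changes with laser and with bur were then set side by side. Of the genes called against control, 1481 were higher and 2605 lower with both, and 0 were called in opposite directions. They made up 80.7% of the laser calls and 68.7% of the bur calls. Ccl7, Ccl12, Cxcl3 and Pax1 were among the largest rises with both, and Lep, Suv39h2, Ecel1, Pck1 and Gys2 among the largest falls. Both comparisons used the same 4 control arrays. Data simulated without effect, with all arrays drawn anew and genes independent, shared 0 genes in either direction in 20 draws. The same held with same-numbered arrays correlated as observed. Without an effect hardly any gene is called, so these draws do not show what the real control arrays, which differ more among themselves, would cause. Independent lists of these lengths would share 210.1 and 478.9. Across genes, which are not independent replicates, the log2 changes correlated at 0.935, against 0.50 simulated with independent arrays and 0.54 with same-numbered arrays correlated. Their covariance was 0.508, against 0.048 and 0.043 simulated, a difference of 0.459 from the first. With 2 control arrays for each comparison the median correlation over 6 splits was 0.758 and the median covariance 0.449. Then 47 to 130 genes were higher and 206 to 437 lower with both. Fewer control arrays in a comparison also leave fewer calls, so these counts do not show how much the shared controls add. Without control replicate 1 the shared counts were 343 and 726, without laser replicate 2 they were 429 and 770, without laser replicate 3 they were 476 and 954, without control replicate 4 they were 643 and 1012, without laser replicate 4 they were 848 and 1488, and without bur replicate 3 they were 926 and 1703. Without bur replicate 1, 889 were higher with both, without bur replicate 4, 966 were, and without control replicate 3, 3060 were, while without control replicate 2, 1716 were lower with both.

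**Figure D3:**
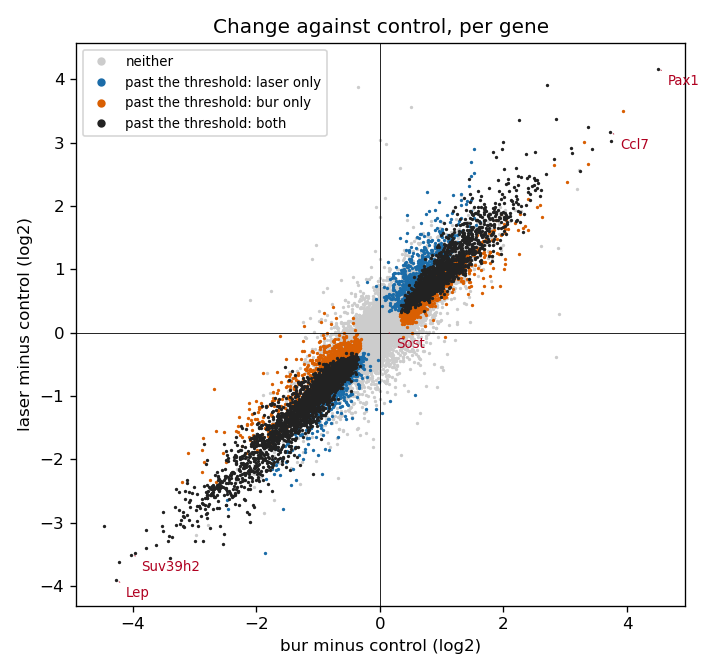
Log2 change against control of each of the 22718 genes, bur on the horizontal and laser on the vertical axis, coloured by which comparison passed the adjusted p of 0.05. Genes past the threshold in both comparisons lie along the diagonal, from Lep and Suv39h2 to Ccl7 and Pax1, and Sost lies near 0 on both axes.

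Laser-ablated bone was compared with bur-drilled bone to see whether the 2 ways of removing bone differed. No gene passed in limma (0 higher and 0 lower), the smallest adjusted p being 0.43. At an unadjusted p under 0.05 there were 574 genes, and the groups did not overlap for 2.15% of genes. By chance this would be 2.86% for unpaired arrays, and that share does not take the pairing into account. The authors' own comparison table also calls 0 and 0. Without the filter on detection 1 gene passed, Muc15, a mucin gene outside the naming rule and chosen after its value was seen, at 2.55 (SE 0.28, limma adjusted p = 0.041).

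As lists, osteoblast, osteocyte, Wnt target and BMP and TGF-beta genes stood higher with laser. Of 18 osteoblast and bone matrix genes 17 had a positive difference, with a mean of 0.40, and 2 passed when adjusted over the list alone (camera adjusted p = 4.3e-09; adjusted p = 0.47 with an estimated correlation). Sp7, which encodes the osteoblast transcription factor osterix, differed by 0.60 (SE 0.14, interval 0.29 to 0.91). Of 9 osteocyte genes 8 were positive (camera adjusted p = 0.0021; adjusted p = 0.54 with an estimated correlation), with Phex at 0.73 (SE 0.30). Of 10 Wnt target genes 9 were positive (camera adjusted p = 0.0030; adjusted p = 0.13 with an estimated correlation), with Axin2 at 0.43 (SE 0.16). Of 16 BMP and TGF-beta genes 11 were positive (camera adjusted p = 0.036; adjusted p = 0.47 with an estimated correlation; adjusted p = 0.066 with the replicate block), with Tgfb1 at 0.50 (SE 0.21).

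Other lists stood lower with laser than with bur. Negative differences were seen for 12 of 14 osteoclast genes (camera adjusted p = 0.033; adjusted p = 0.78 with an estimated correlation) and 10 of 13 T cell and NK cell markers (camera adjusted p = 0.018; adjusted p = 0.47 with an estimated correlation). They were also seen for 8 of 10 mast cell markers (camera adjusted p = 0.033; adjusted p = 0.78 with an estimated correlation) and 11 of 15 heat shock genes (camera adjusted p = 0.018; adjusted p = 0.47 with an estimated correlation). Of 16 respiratory chain genes 15 were negative (camera adjusted p = 0.033; adjusted p = 0.78 with an estimated correlation). Single values were -0.66 (SE 0.43) for Dcstamp, -0.57 (SE 0.32) for Gzmb, -0.39 (SE 0.27) for Cpa3, -0.15 (SE 0.12) for Cyc1 and -0.44 (SE 0.18) for Hsp90aa1, with that sign in 2 of its 3 kept probes. With normexp Gzmb (0.08), Dcstamp (0.13) and the mean of the T cell and NK cell list (0.04) turned positive. The median of all genes then moved to 0.13, and none of these lay above it. In none of these lists except that of osteoblast and bone matrix genes did a member pass, adjusted over the list alone or over all genes. The skeletal muscle mean, high on replicate 1 of each group, was 2.72 on bur replicate 1 and 0.98 on laser replicate 1.

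Among these lists, the call for osteoblast and bone matrix genes and that for Wnt target genes held whichever array was left out. Without bur replicate 2 the osteocyte list (camera adjusted p = 0.067) lost its call. The T cell and NK cell list did so without bur replicate 1 (0.056) or 2 (0.16) or laser replicate 2 (0.16), and the mast cell list without bur replicate 2 (0.38) or laser replicate 2 (0.44) or 3 (0.43). The BMP and TGF-beta list did so without bur replicate 1 (0.11) or 2 (0.094), laser replicate 2 (0.094), 3 (0.054) or 4 (0.10), or control replicate 3 (0.057). The osteoclast list did so without laser replicate 2 (0.26), laser replicate 3 (0.39), bur replicate 3 (0.25) or bur replicate 4 (0.34). The heat shock list did so without laser replicate 1 (0.19) or bur replicate 3 (0.24), and the respiratory chain list without laser replicate 1 (0.44), laser replicate 3 (0.27) or bur replicate 4 (0.37). Other settings ended calls too. The Wnt target list did not pass with normexp (0.051) or without the detection filter (0.22), nor did the BMP and TGF-beta list (0.32 and 0.24), which also did not pass with detection on all 12 arrays (0.068) or with the marrow score as covariate (0.061). The osteoclast list did not pass with quantile normalization (0.070), detection on all 12 arrays (0.051) or array weights (0.066), and the respiratory chain list did not with quantile normalization (0.13), the deposited table (0.16) or array weights (0.069). The mast cell list did not pass with quantile normalization (0.055).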

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

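Within each group of 4 arrays, the highest or lowest array was compared with the others by Dixon's test, for 354 groups of values. It singled out 19, and chance alone singles out about 1 group in 20. Values are log2 signals relative to the array's 75th percentile for genes, and means relative to the 12 arrays for lists.

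Sost was at -4.25 on laser replicate 2, far below the other 3 laser arrays. Among chemokine genes, Cxcl3 was high on bur replicate 3 at -0.50, while Ccl7 at -0.53 and Ccl12 at -0.51 were low on bur replicate 4. Rln1 was low on laser replicate 1 at -4.43. Anxa8 was low on control replicate 4 at -8.82, and Phlda3 on control replicate 2 at -7.93. Among blood cell markers, S100a9 was low on control replicate 3 at 6.38, Gata1 was high on laser replicate 1 at -1.67, and Cd247 was low on bur replicate 4 at -4.30 and high on control replicate 1 at -2.05. Rsad2, an interferon response gene, was high on laser replicate 1 at 3.03.

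The skeletal muscle list was high on replicate 1 of all 3 groups, at 3.37 in control, 2.72 in bur and 0.98 in laser. The osteocyte list was low on bur replicate 2 at -0.47. On bur replicate 3 the hypoxia and glycolysis list stood high at 1.08 and the p53 target list at 0.27. Added spike-in RNA, relative to the 75th percentile, was low on bur replicate 2 at -0.15. Laser replicate 4 was lower still, at -0.84, and laser replicate 2 was at 0.20, while the other 9 arrays were at 0.76 to 1.17.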

How the results depend on the processing

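The marrow score covariate and the exact permutation of list means were chosen after the data were seen. Numbers are genes higher then lower unless stated, and the cause of a shift was not tested unless named. Signal over background limits the dim genes, and the 5 named genes given as a bound in laser against control (Pax1, Lipi, Slc27a5, Oasl and Pck1) did not pass with normexp background correction.

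With normexp, 1187 genes were higher with laser than control, 6306 were lower with bur, 941 were higher with both, and 14 lists passed between laser and bur. The median of all genes then moved to -0.08, -0.24 and 0.13 in the 3 comparisons, relative to which these changes stand. Without taking that shift off, Sost turned to -0.084, -0.11 and 0.022, Axin2 (laser minus control) to -0.026, Tnfsf11 (bur minus control) to -0.15, and Gzmb, Dcstamp and the T cell and NK cell list (laser minus bur) to 0.079, 0.13 and 0.041. Without a detection filter, which tested 34912 genes, the counts were 1199 higher with laser, 5750 lower with bur, 940 higher with both, and 1 higher with laser than bur. With array weights they were 3534 higher with laser, 3631 higher with bur and 2632 higher with both. Fits on the 2 groups compared, with fewer arrays behind the spread, gave 651 and 1107 with laser, 1483 higher with bur, and 468 and 998 with both. Requiring at least a 2-fold change left 902 and 1477 with laser and 913 and 1687 with bur.

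With the marrow score as covariate the counts were 2 and 0 with laser, 0 and 0 with bur, and 0 and 0 with both, and 3 and 1 lists passed against control. These were the osteocyte (camera adjusted p = 0.046), mast cell (0.0062) and adipocyte lists (0.0016) with laser and the adipocyte list (0.025) with bur. Of the 2 genes 1 was Slc6a3 (2.93), outside the naming rule and chosen after its value was seen. Sost, laser minus control, turned to -0.031. For laser minus control Mki67 turned to 0.17, and the means of the neutrophil, B cell, cell cycle and hypoxia lists to 0.049, 0.16, 0.13 and -0.054. For bur minus control Mki67 turned to 0.24, Pdpn to -0.010 and Arg1 to -0.32, and the means of the neutrophil, B cell, cell cycle, hypoxia, osteoclast regulator, fibrous matrix and heat shock lists to 0.10, 0.14, 0.17, -0.015, -0.090, -0.060 and -0.015. The neutrophil and B cell lists are part of the score itself.

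With an estimated correlation camera called 0 lists in each comparison, and the exact permutation of list means called 0 after adjustment in each. At an unadjusted exact permutation p under 0.05 it gave 8, 5 and 2 lists. Limma's fry called 10 lists with laser, 6 with bur and 0 between laser and bur. Those it called and camera did not were the p53 targets with laser (fry adjusted p = 0.029) and bur (0.0052) and the BMP and TGF-beta genes with laser (0.044).

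Other settings let pass lists that camera had not called, given here by camera adjusted p. Against control with laser these were the cytokine and chemokine (0.039), heat shock (0.028) and BMP and TGF-beta lists (0.024) with normexp, and the last also without the detection filter (0.023) or without control replicate 1 (0.032) or 2 (0.043). With bur they were the YAP/TAZ (0.0052), cytokine and chemokine (0.0035), respiratory chain (0.0059), p53 (0.016) and interferon lists (0.0026) with normexp, and the YAP/TAZ (0.027), cartilage (0.047), cytokine and chemokine (0.0056), p53 (0.012) and interferon lists (0.024) without the filter. The mean of probes added the cytokine and chemokine (0.042) and interferon lists (0.028), and array weights the interferon list (0.033). Single arrays added the YAP/TAZ (0.042, without control replicate 3), p53 (0.034, without control replicate 2) and interferon lists (0.0016, without bur replicate 4). Between laser and bur the lists added numbered 8 with normexp, 4 with array weights, 3 without the filter, 3 with only the 2 groups, and 10 without bur replicate 4, and at most 5 under any other setting. An estimated correlation was not run with these settings.

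With the replicate number as a block the counts were 2455 and 3316 with laser, 2602 and 3976 with bur, and 0 and 0 between them, and 15, 13 and 12 lists passed. It ended the calls of Csf1, Axin2 and the T cell and NK cell list with laser (adjusted p = 0.053, 0.0502 and 0.057) and of the BMP and TGF-beta list between laser and bur (0.066). It added calls of the skeletal muscle list with laser (camera adjusted p = 0.010), of the inflammatory cytokine and chemokine list with bur (0.027), and, between laser and bur, of the inflammatory cytokine and chemokine (0.0499), macrophage and monocyte (0.0499), skeletal muscle (1.1e-04) and Schwann cell lists (0.0499). It changed no other call of a named gene or a list. With the block and an estimated correlation no list passed. The slide as a block could not be fitted.

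Leaving out each array in turn, the lowest and highest counts were 449 and 3861 genes higher and 796 and 4133 lower with laser, 878 and 3794 higher and 1911 and 4603 lower with bur, and 0 and 0 in both directions between laser and bur. For genes changed with both they were 343 and 3060 higher and 726 and 3761 lower. For lists they were 11 and 15, 8 and 14, and 5 and 17. Sost ranged from -0.12 to 0.38, -0.063 to 0.27 and -0.25 to 0.28, with adjusted p over all settings of 0.301 to 0.996, 0.460 to 0.985 and 0.977 to 1. Quantile normalization, the deposited table, the stricter filter, the mean of probes, the percentile over detected probes and the intensity trend kept all counts of genes within 1.5 times. Over the settings other than left-out arrays, named genes in laser against control gave 676 values, of which 561 kept their direction and side of the threshold, 113 lost the threshold and 2 turned, and in bur against control 586, of which 516, 66 and 4 did.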

Other observations

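The spike-in comparison, the restriction to splits that part all same-numbered arrays, the count of control arrays within the treated range, the comparison of structural with other bone genes and the marrow score covariate were tests chosen after the results they bear on were seen, and the megakaryocyte and progenitor lists were written after the fall of marrow markers but before their own values.

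Members of further lists changed with both treatments, in both directions, and camera called none of these lists with the processing first chosen. Of 22 inflammatory cytokine and chemokine genes 7 rose and 3 fell with laser, and 11 and 3 when adjusted over the list alone (camera adjusted p = 0.21), while 8 rose and 2 fell with bur, and 9 and 2 when adjusted over the list alone (camera adjusted p = 0.057, and 0.027 with the replicate block, where with an estimated correlation the smallest of any list was 0.53). Csf3 fell by 3.04 with laser (SE 0.42), against the direction of most members that changed, and Il11 differed by 1.37 between laser and bur (SE 0.53, limma adjusted p = 0.9998). Of 12 p53 target genes 4 rose and 2 fell with laser, and 5 and 2 when adjusted over the list alone (camera adjusted p = 0.23, fry adjusted p = 0.029), while 5 rose and 2 fell with bur, the same when adjusted over the list alone (camera adjusted p = 0.072, fry adjusted p = 0.0052). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.39 with laser (SE 0.30) and 1.15 with bur (SE 0.30), and Phlda3 by 1.75 (SE 0.41) and 2.27 (SE 0.41). Of 12 immediate early genes 2 rose and 1 fell with laser, and 3 and 3 when adjusted over the list alone (camera adjusted p = 0.44), and 3 rose and 3 fell with bur, the same when adjusted over the list alone (camera adjusted p = 0.34), with Fos at 1.87 (SE 0.48) and 2.33 (SE 0.48) and Junb at 0.90 (SE 0.18) and 0.88 (SE 0.18). With normexp Phlda3 (0.23 and 0.30) and Junb (0.29 and 0.12) did not pass.

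Wnt pathway genes, the pathway that sclerostin inhibits, moved both ways. Of 10 Wnt target genes 1 rose and 1 fell with laser, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.36). With bur 3 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.84). Nkd1 fell by 1.57 with laser (SE 0.21) and fell by 1.74 with bur (SE 0.21), and Apcdd1 fell by 0.98 with bur (SE 0.21). Axin2 rose by 0.53 with laser (SE 0.16, limma adjusted p = 0.036), and passed in 6 of the 12 fits that each left out an array. It did not pass with the replicate block (0.0502), the deposited table's values (0.068), no detection filter (0.066), an intensity trend (0.072) or these 2 groups alone (0.072). With normexp it was at -0.03, where the median of all genes moved to -0.08. Of 10 secreted Wnt inhibitors 2 rose with laser, Dkk1 by 1.28 (SE 0.30) among them, and 3 when adjusted over the list alone (camera adjusted p = 0.17), and 1 fell with bur, the same when adjusted over the list alone (camera adjusted p = 0.34). Between laser and bur Notum, another inhibitor, differed by 1.13 (SE 0.32, limma adjusted p = 0.9998; list camera adjusted p = 0.14).

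Camera did not call the following lists with the processing first chosen. In laser against control, camera adjusted p was 0.89 for osteoclast genes, 0.061 for BMP and TGF-beta genes (fry adjusted p = 0.044), 0.25 for YAP/TAZ targets, 0.23 for heat shock genes and 0.84 for respiratory chain genes. In bur against control it was 0.54 for osteoclast genes, 0.34 for BMP and TGF-beta genes, 0.11 for YAP/TAZ targets, 0.34 for respiratory chain genes, 0.11 for cartilage genes, 0.084 for interferon response genes and 0.34 for T cell and NK cell markers. For endothelial, skeletal muscle, keratinocyte, neuron and glia, meningeal and Schwann cell markers it was 0.47, 0.27, 0.54, 0.36, 0.34 and 0.30 with laser and 0.76, 0.76, 0.62, 0.58, 0.56 and 0.76 with bur. In laser against bur those were 0.30, 0.068, 0.996, 0.53, 0.50 and 0.070, and the other lists not given elsewhere were between 0.070 and 0.9997. With the replicate block the skeletal muscle list was lower with laser than control (0.010), and the skeletal muscle (1.1e-04), Schwann cell (0.0499), inflammatory cytokine and chemokine (0.0499) and macrophage and monocyte lists (0.0499) were lower with laser than bur. With the block and an estimated correlation no list passed, the smallest adjusted p being 0.47 and 0.31 in these comparisons. The meningeal mean was highest on control replicate 2 (2.22), bur replicate 1 (1.47) and control replicate 1 (0.82). Median and mean of a list differed in sign for respiratory chain genes in laser against control (-0.04 and 0.01), Wnt target genes in bur against control (0.15 and -0.11) and adipocyte markers in laser against bur (0.10 and -0.01). For erythroid (0.03) and keratinocyte markers (0.00) in laser against bur, median and mean were above 0 and the test pointed down.

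Many genes differed between control and treated arrays, and since the numbers pair laser with control arrays, the real laser split was compared with those that part all same-numbered arrays: 1 of 8, the real one, called as many as 5061 genes and the highest other 0, but 8 splits are too few for a share under 0.05. Over all 35 splits the highest other called 2795, and differed from the real one only by exchanging laser replicate 1 with control replicate 3. It set the 4 arrays with marrow scores of at least 0.134 against 4 of at most 0.108. Since it mostly keeps the real groups, it cannot tell a structure by marrow score from the difference between the groups. Of 35 splits of bur and control arrays only the real one, 1 split, called as many as 5948 genes, the highest other calling 1418. This share is under 0.05, the smallest that 35 splits allow, and argues against chance only if bur and control arrays are unpaired. Of the splits that part all same-numbered arrays the 7 others called at most 0, but these are again too few for a share under 0.05. For the signals of the 6 spike-in RNAs used here, an intensity-dependent difference between the slides is argued against. Their largest difference relative to the other spike-ins was 0.118 on the log2 scale, against a median change of 0.96 and 0.92 among called genes. Their mean signal was -0.84 to 1.17 relative to the array's 75th percentile, so a difference confined to dim probes stays open. A labelling or hybridisation batch that goes with the slide cannot be told apart from the treatments, since adding the slide to the model loses 1 column of it, and an effect of ablation stays open beside it.

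Between laser and bur limma called 0 genes, with 574 at an unadjusted p under 0.05, so 8 of the 8 splits that part all same-numbered arrays called as many (highest other 0), as any split must, and nothing about chance follows from them.

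A hypothesis for the lower blood cell markers is that treated samples may have held a smaller share of marrow, since abundant marrow transcripts fell, S100a9 from 7.44 in control to 5.91 with laser and Camp from 6.33 to 4.42 with laser and 4.45 with bur. On lists not looked at before, megakaryocyte markers had medians of -1.55 with laser and -2.02 with bur (9 measured, 8 negative with each). Progenitor markers had medians of -0.42 and -0.29 and mixed signs (8 measured, 3 positive and 5 negative with each). Of these, 1 was called higher and 2 lower with laser, and 0 higher and 2 lower with bur. The highest median, -0.29, missed the bound of -0.3 that a smaller marrow share would need, yet lay below the 0 that would argue against it. For a sample property that control arrays share only with their slide, 1 control array, replicate 3 at 0.11, lay inside the treated range of -1.20 to 0.13, but a single array excludes nothing. With the score in the model 97.5% of the laser calls and 97.8% of the bur calls kept their sign, and the calls ended because changes fell to 0.43 and 0.47 while SEs grew to 0.29 and 0.28, with 64.2% of the variance of the score lying between groups. Marrow share, slide and a response of bone to ablation cannot be told apart here.

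Another hypothesis is that laser-ablated bone may hold more osteoblast transcripts than bur-drilled bone at 72 h. The mean of the osteoblast and bone matrix list was 0.401 higher with laser, in 4 of 4 same-numbered pairs, and of the 8 splits that part all pairs only the real one, 1 split, gave a difference as large (highest other 0.355), but 8 are too few for a share under 0.05, and over all 35 splits 2 gave one as large (highest other 0.471, exact permutation p = 0.057). If the laser samples held a larger share of bone, the 4 abundant structural genes Col1a1, Col1a2, Bglap and Sparc would be higher by as much as the other 14 members, and they were higher by 0.207 against 0.457, a difference of 0.25 with an exact permutation p of 0.143 over all 35 splits, which leaves that share open. Markers of another cell type stood higher too, with 9 of 9 members of the megakaryocyte list higher with laser than bur and a median of 0.37. Members are not independent replicates, so the SEM of 0.14 over members does not measure the spread between arrays, and the list was not tested. A change of osteoblast genes alone is therefore not shown. Position on the slide cannot be told apart either, since adding the slide column to the model loses 1 column, and the list's mean was 0.40 with the marrow score as covariate.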
